A study of Mus musculus with 24 samples.

How the data were processed

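RNA was measured in 4 cell populations sorted from mouse hindlimb muscle, each from uninjured muscle and from muscle taken 1 day after injection of cardiotoxin. The populations were CD45+ cells (hematopoietic cells), CD31+ cells (endothelial cells), mesenchymal stromal cells (MSC; without CD45 and CD31, with Sca1 and PDGFRa) and muscle stem cells, also called satellite cells (MuSC; without CD45, CD31 and Sca1, with Vcam1). Each of the 8 groups had 3 libraries, 24 in all. Per the labels' protocols, about 1000 cells per library were sorted and then sorted again, RNA was copied from an oligo(dT) primer, the cDNA was amplified by PCR and tagged with Nextera XT, and paired reads of 25 bases were sequenced. These steps do not mark the strand and, as described in the labels, carry no molecular identifiers. Reads from overlapping genes on opposite strands can therefore not be told apart, and copies made by PCR are counted as separate reads.

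The authors deposited a table of raw read counts per gene symbol, whole numbers with no normalization, for 52997 symbols and 24 libraries. Per the submitters' processing notes, STAR 2.5.4, featureCounts and the mouse genome mm10 were used. The version and settings of featureCounts, the treatment of reads that match several genes and the gene annotation are not given in the sources used here. Values of near-identical genes are uncertain for that reason, among them the chemokine genes Cxcl1, Cxcl2 and Cxcl3, immunoglobulin variable genes, ribosomal protein genes with processed pseudogenes, Hspa1a and Hspa1b, and mitochondrial genes with nuclear copies. Positions were taken from GENCODE vM21 on GRCm38, the assembly of mm10: 49365 symbols matched a gene name there and 3632 did not.

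The count table went into edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and the data.table package (1.17.8). Genes with too few counts for the group size were removed by edgeR's filter over the 8 groups, which left 16263 genes. Library sizes were scaled by TMM, 1 model with a mean for each group was fitted to all 24 libraries (16 residual degrees of freedom), and edgeR's quasi-likelihood test with robust estimation gave each p. Fitting all groups together shared 1 estimate of the spread, whose common biological coefficient of variation was 0.224 and whose prior had a median of 7.36 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 counted as passing. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic and are approximate. Values in CPM were computed by edgeR on the TMM-scaled library sizes and are given as mean ± SD over 3 libraries unless stated.

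Comparisons were of 3 kinds. A gene was counted as highest in an uninjured population when it passed the test against each of the other 3 with the higher value there. Injury was tested within each population, injured against uninjured. Differences between populations in their response to injury were tested by an F test on 3 degrees of freedom over all populations and, for each population, by its injury effect minus the mean injury effect of the other 3. For a gene with 0 counts in every library of a group, edgeR can return a p of 1 for these differences even where the fitted difference is large; such genes were kept with that p. Gene lists for cell types, pathways and processes (59 written, 56 with at least 5 members measured and tested) were tested with camera at a preset correlation between genes of 0.01, adjusted over the 56 lists. Each list was tested again with its correlation estimated from the data. Fry was run too, which asks whether the genes of a list move one way on balance and does not compare them with other genes. For each list the count of members that passed is given over all genes tested and adjusted over the list alone.

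The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for injury in each population, the 8 largest rises and 6 largest falls among genes that passed, had a mean of at least 20 CPM in the higher group and had no overlap between the libraries of both conditions. It added the 8 largest rises of genes with a higher level than in injured CD45+ cells, up to 4 members of each called list by smallest adjusted p, and the same for the identity list of each population. It further took the 5 genes of the sort gates, the 8 genes most specific to each uninjured population, and the 4 largest differences in response in each direction. Unnamed gene models were left out, and 1 gene among the largest rises in MSC is not reported here. Other names are stated as chosen after their values were seen.

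Library totals ranged from 2301000 to 7650000 counts, so that 3 counts, taken as the limit that a count of 0 allows, equal 0.392 to 1.30 CPM in a single library. Where all libraries of a group had 0 counts, the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts in a group the ratio of pooled counts is given with its 95% counting interval. Intervals and limits cover counting error only, since PCR copies are not independent molecules. The code was tested on simulated counts for 15541 genes with the real library sizes and with means pooled over both conditions of each population. Genes changed in CD31+ were drawn from well-counted genes there and outside the lists, so their recovery does not hold for genes with few counts. Genes raised in uninjured MuSC were first set to 1 level in all groups. For injury in CD31+ the code recovered 64 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, and 4 of its 177 calls were unchanged genes. For the difference in response of CD31+ it recovered 53 and 89 of 100, for the F test over populations 40 and 83, and for genes highest in uninjured MuSC 54 and 84. No call was made in MSC, where no gene was changed.

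The alternatives were DESeq2 1.42.0, DESeq2's size factors (RLE) in edgeR, no filter on low counts, limma's voom with quality weights, a test against a 2-fold change (glmTreat), fits of only the libraries compared, the muscle number as a block, genes higher in injured CD45+ cells left out, and each library left out in turn. Principal components were computed on the log2 CPM (prior count 2) of the 2000 most variable genes. No library was left out of the results as given.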

Results

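Gene expression was profiled by RNA sequencing in cells sorted from the hindlimb muscle of C57BL/6 mice aged 8 weeks. Muscle was taken uninjured or 1 day after injection of cardiotoxin, a snake venom toxin that destroys muscle fibers and starts a round of repair by resident stem cells. CD45+ hematopoietic cells, CD31+ endothelial cells, MSC and MuSC were collected, which gave 8 groups of 3 libraries. The labels call the 3 libraries of a group biological replicates. They do not say whether libraries with the same number came from the same mouse, and p-values measure the spread between these libraries. Total counts per library ranged from 2301000 to 7650000. In megacounts, group means (± SD, n = 3) for uninjured and injured cells were 3.74 ± 0.791 and 5.82 ± 0.633 in CD31+ and 3.80 ± 0.590 and 4.94 ± 0.218 in CD45+. They were 6.07 ± 1.38 and 6.28 ± 0.898 in MSC and 3.54 ± 1.08 and 6.37 ± 0.740 in MuSC. Between 19000 and 27730 gene symbols had at least 1 count in a library.

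The libraries grouped first by cell population and then by injury. Pearson's r of log2 CPM across genes was 0.949 to 0.985 in the 24 pairs of libraries within groups, and at most 0.937 between groups. The transcripts of the sort markers followed the gates. Ptprc, which encodes CD45, was at 783.5 ± 84.9 CPM in uninjured and 482.5 ± 60.3 CPM in injured CD45+ cells, and at most 5.40 CPM on average elsewhere. Pecam1, which encodes CD31, was at 2052 ± 152 and 1946 ± 118 CPM in CD31+ cells. Ly6a, which encodes Sca1, was at 2886 ± 217 and 2029 ± 480 CPM in MSC and at 2368 ± 278.5 and 2869 ± 308 CPM in CD31+ cells, and Pdgfra was at 568 ± 40.2 and 653 ± 71 CPM in MSC. Vcam1 had its highest mean in MuSC, 602 ± 61.55 CPM uninjured and 405 ± 42.3 CPM injured. Transcripts that mark other populations were uneven between the replicates of some groups, and their source was not settled. Pdgfra was at 0.298, 48.8 and 25.4 CPM in the 3 injured MuSC libraries and at 6.31 CPM in 1 injured CD45+ library (replicate 3), whose other replicates had none. Lyz2, a transcript of myeloid cells, was at 108 CPM in injured CD31+ replicate 1 against 1.75 and 0.159 CPM in replicates 2 and 3.

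**Figure D1:**
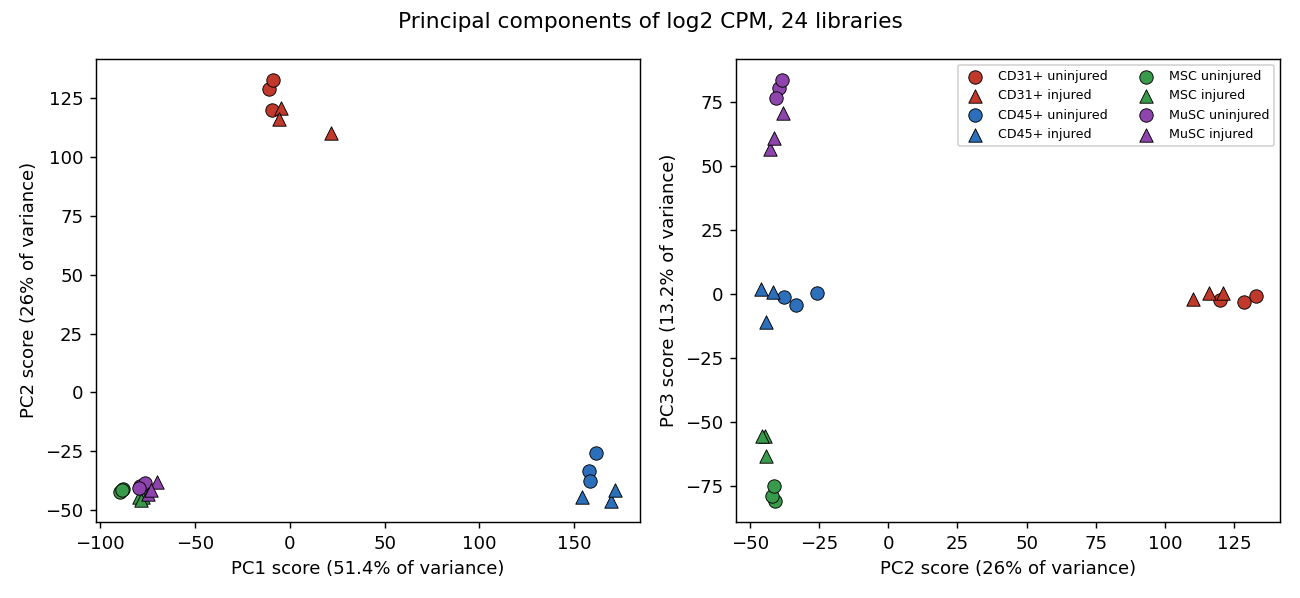
Scores of the 24 libraries on principal components 1 and 2 (left) and 2 and 3 (right), computed on log2 CPM; colors mark the sorted population, circles uninjured and triangles injured muscle. Components 1 to 3 hold 51.4%, 26% and 13.2% of the variance and part CD45+, CD31+, and MSC from MuSC libraries in that order.

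**Figure D2:**
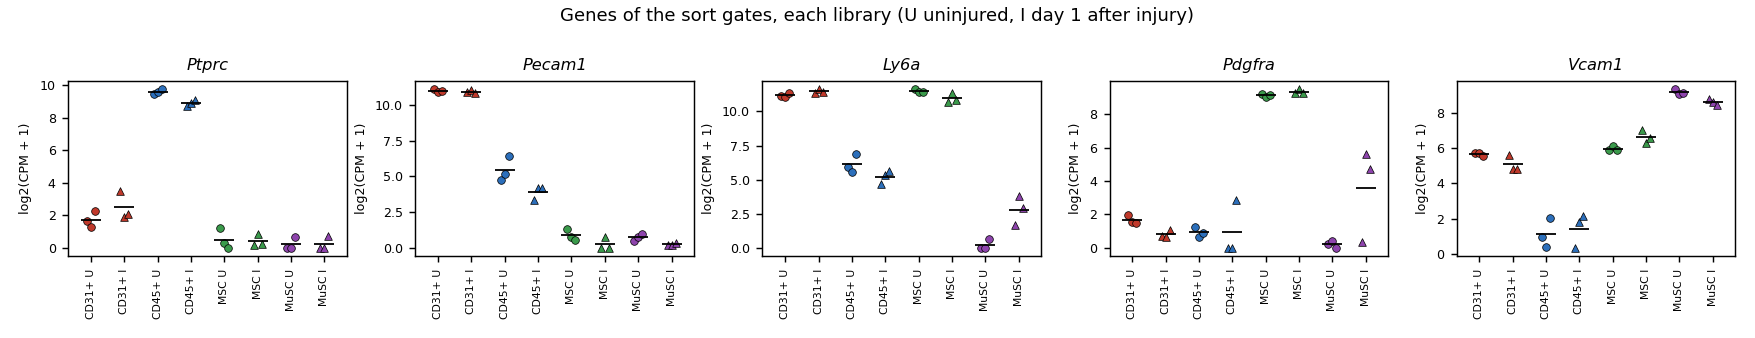
Expression of the 5 genes that encode the sort markers, as log2(CPM + 1), in each library of the 8 groups (U, uninjured; I, injured); points are libraries and bars are means. Ptprc is highest in CD45+, Pecam1 in CD31+, Pdgfra in MSC and Vcam1 in MuSC libraries, and 2 injured MuSC libraries hold Pdgfra at 48.8 and 25.4 CPM.

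The first comparison asked which genes set the populations apart in uninjured muscle. Each sorted population carried the genes of its cell type. All 15 satellite cell genes were highest in MuSC, all 15 stromal genes in MSC, all 14 endothelial genes in CD31+ and all 14 leukocyte genes in CD45+ cells. In MuSC the transcription factors of the muscle lineage Pax7, Myf5 and Myod1 stood at 574 ± 69.6, 454 ± 39.9 and 349 ± 73.1 CPM, with the receptors Fgfr4 at 635 ± 38.9 and Calcr at 414.5 ± 27.1 CPM and the adhesion molecule Cdh15 at 1342 ± 145 CPM. These 6 genes passed against each other population, with the largest adjusted p at 1.31e-08 (Pax7), and had at most 1.25 CPM on average in the other uninjured populations. CD31+ cells carried the Notch ligand Dll4 (474 ± 50.2 CPM), the receptor Tie1 (1117 ± 155), the glycerol channel Aqp7 (1133 ± 90.2) and the transcription factor Tcf15 (67.6 ± 15). CD45+ cells carried the antigen presentation genes H2-Ab1 (17920 ± 1602 CPM), H2-Aa (9109 ± 971.5) and Cd74 (11170 ± 1075), lysozyme Lyz2 (15850 ± 2024) and the complement gene C1qc (2340 ± 892). MSC carried the matrix genes Smoc2 (5068 ± 774 CPM), Efemp1 (1557 ± 245) and Podn (743 ± 86.6), the secreted factor Gdf10 (763 ± 234) and Myoc (5534 ± 1057).

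By this test, 2221 of 16263 genes were highest in uninjured CD45+, 1614 in CD31+, 1479 in MSC and 1282 in MuSC, of which 1687, 1171, 1035 and 708 were over 2-fold above each other population. Among lists of blood cell types, 9 of 9 B cell, 12 of 13 T cell, 7 of 7 natural killer (NK) cell, 11 of 13 neutrophil and 13 of 14 resident macrophage genes were highest in CD45+ cells. Muscle fiber transcripts were in every uninjured population, with a median of 31.4 CPM over 14 genes in MuSC, 16.6 in MSC, 7.77 in CD45+ and 7.66 in CD31+ cells.

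The second comparison, made within each population, asked what changed 1 day after injury. In CD31+ cells 2298 genes rose and 1512 fell, in CD45+ cells 2594 rose and 3012 fell, in MSC 2977 rose and 3831 fell, and in MuSC 3477 rose and 2841 fell. Changes over 2-fold were made by 1049 and 830 of these in CD31+, 1092 and 2251 in CD45+, 1725 and 2663 in MSC, and 2118 and 1777 in MuSC. Of all 16263 genes tested, injured and uninjured libraries did not overlap for 37.3% in CD31+, 43% in CD45+, 55% in MSC and 49.5% in MuSC, where chance gives 10%. The split between rises and falls depended on the scaling of libraries. With RLE in place of TMM the median log2 fold change of all genes moved from -0.04 to -0.15 in CD31+ cells (1926 rose and 2058 fell, 48.3% against 60.3% rising), from -0.12 to -0.13 in CD45+ cells (2571 and 3052), from -0.22 to -0.30 in MSC (2674 and 4292, 38.4% against 43.7% rising) and from -0.04 to -0.13 in MuSC (3165 and 3284). In MuSC as in CD31+ cells more genes rose than fell with TMM and more fell than rose with RLE. No gene list described here changed the sign of its median with RLE.

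In endothelial cells (CD31+) injury was followed by higher transcripts for ribosome production (21 of 21 genes), of heat shock proteins (6 of 12) and of matrix proteases and their inhibitors (8 of 17). These lists were called with either correlation (adjusted p = 0.000198, 0.0414 and 0.0359 with an estimated correlation). Myc, which encodes a transcription factor that drives cell growth (chromosome 15, 61985391 to 61990374, GRCm38), rose from 14.4 ± 0.498 to 261 ± 43.3 CPM (log2 fold change 4.17 ± 0.16 SE, adjusted p = 2.37e-14). Pgf, which encodes a ligand of the VEGF family (chromosome 12, 85166635 to 85177790), rose from 12.2 ± 8.62 to 692 ± 214 CPM (5.78 ± 0.41, adjusted p = 3.12e-09). Kdr, which encodes the main VEGF receptor (chromosome 5, 75932827 to 75978458), fell from 834 ± 76.3 to 378 ± 12.3 CPM (-1.14 ± 0.23, adjusted p = 0.000977). Irf7, a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481), fell from 206 ± 14.1 to 83.2 ± 8.75 CPM (-1.31 ± 0.22, adjusted p = 6.97e-05).

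All 21 ribosome biogenesis genes rose in CD31+ cells (21 adjusted over the list alone), among them Rrp9 by 2.26 on the log2 scale. The list was called with the preset correlation (adjusted p = 2e-44) and with an estimated one (0.000198). All 21 cytosolic ribosomal protein genes rose (21 adjusted over the list alone), with a median of 0.94 log2; Rplp0 went from 734 ± 17.4 to 1612 ± 177 CPM. That list's call did not hold with its own correlation (adjusted p = 0.0672 with an estimated correlation). Of 12 heat shock genes 6 rose (7 adjusted over the list alone), such as the mitochondrial chaperonin Hspd1 from 44.0 ± 3.91 to 186 ± 24 CPM (2.08 ± 0.12, adjusted p = 1.78e-11) and Hspa8, and the call held (adjusted p = 0.0414 with an estimated correlation). Of 17 matrix proteases and inhibitors 8 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation). The urokinase receptor Plaur rose from 8.65 ± 3.94 to 143 ± 29.0 CPM, its ligand Plau by 2.33 and Adamts4 by 4.87 on the log2 scale, while Mmp2, named after its values were seen, fell by 1.65. The interferon-stimulated genes fell in 18 of 21 cases (18 adjusted over the list alone), with Gbp3 at -1.64 and Cmpk2 at -1.59 log2 (list adjusted p = 9.72e-10, but adjusted p = 0.0672 with an estimated correlation). Among the other calls that the estimated correlation ended were those of 12 of 16 glycolysis genes rising (adjusted p = 0.193 with an estimated correlation), 18 of 25 oxidative phosphorylation genes rising (20 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation) and 12 of 17 genes of the unfolded protein and integrated stress response rising, such as Atf4 by 1.64 (adjusted p = 0.0761 with an estimated correlation). In the glycolysis list 1 gene fell, as did 1 in the stress response list.

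The largest rises in CD31+ cells included genes with few counts before injury. Ankrd1, which encodes an ankyrin repeat protein, had 1 count in uninjured libraries and 836 in injured ones (ratio 542, 95% counting interval 97 to 21430). Bmp2, a growth factor gene (chromosome 2, 133552159 to 133562885), had 1 and 473 counts (ratio 307, 54.8 to 12140), and Gdf15, a stress-induced cytokine gene, 2 and 432 (ratio 140, 38.5 to 1160). AA467197 rose from 0.432 ± 0.154 to 154.5 ± 44.9 CPM, Sh2d5 from 0.507 ± 0.456 to 143 ± 45.0 CPM and the mitochondrial folate enzyme gene Mthfd2 from 2.38 ± 1.60 to 85.3 ± 24.1 CPM. AA467197 overlaps a microRNA gene, Mir147. The largest falls included Sez6 (-3.15 ± 0.55), the growth factor gene Fgf9 (-2.90 ± 0.67) and Nr3c2, the mineralocorticoid receptor gene (-2.64 ± 0.32, from 28.9 ± 0.790 to 4.58 ± 2.25 CPM). Of the 14 endothelial identity genes 1 rose and 2 fell. The call of Ptprb (-0.93, adjusted p = 0.0381) ended without any 1 of the 6 CD31+ libraries (0.0527 to 0.112), with DESeq2 (0.192) and with no filter (0.266; 5.29e-08 to 1 over all alternatives). Tie1 (-0.77, adjusted p = 0.0641) and Tek (-0.86, adjusted p = 0.0707) did not pass, but did with RLE (0.0325 and 0.0384), voom (2.11e-05 and 0.000335) and the 6 CD31+ libraries alone (0.000103 and 0.000111). Their ranges were 7.08e-06 to 1 and 0.000111 to 1. Of the 14 leukocyte genes 7 rose (9 adjusted over the list alone) and the list was not called (adjusted p = 0.112). Its member Tyrobp was at 24.2 CPM in injured replicate 1 and at 0.582 and 0.159 CPM in replicates 2 and 3.

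In hematopoietic cells (CD45+) the comparison asked how the immune cells of the muscle differed after injury. These cells are a mix of types. The values do not separate a change within cells from a change in that mix, which was not tested. Transcripts of neutrophil chemoattractants (4 of 5 genes), glycolysis (12 of 16) and NRF2 targets (13 of 15) rose, and those of NK cells fell (7 of 7). These lists were called with either correlation (adjusted p = 0.00914, 0.00888, 0.00312 and 0.0469 with an estimated correlation). Arg1, the arginase gene (chromosome 10, 24915221 to 24927484), rose from 12.5 ± 4.14 to 2735 ± 334 CPM (log2 fold change 7.75 ± 0.35, adjusted p = 7.89e-12). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), rose from 37.6 ± 11.8 to 6159 ± 1586 CPM (7.36 ± 1.00, adjusted p = 4.7e-05). Cd79a, part of the B cell receptor (chromosome 7, 24897381 to 24902197), fell from 527 ± 362 to 3.94 ± 4.68 CPM (-7.02 ± 0.72, adjusted p = 9.6e-07).

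All 9 B cell genes fell in CD45+ cells (9 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation), as did 12 of 13 T cell genes (12 adjusted over the list alone; adjusted p = 0.0534 with an estimated correlation) and all 7 NK cell genes (7 adjusted over the list alone), whose call held (adjusted p = 0.0469 with an estimated correlation). Examples are Pax5 at -6.67 log2, Lck from 84.0 ± 45.1 to 2.44 ± 1.16 CPM, and the granzyme gene Gzma from 134 ± 66.9 to 1.71 ± 0.662 CPM (-6.27 ± 0.50, adjusted p = 1.44e-07). Of 10 dendritic cell genes 8 fell, such as Xcr1 and Clec9a, and 1 (Cd24a, named after its values were seen) rose (adjusted p = 0.0963 with an estimated correlation). All 7 MHC class II genes fell (7 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). The class II transactivator gene Ciita went from 214 ± 34.1 to 34.7 ± 6.92 CPM and H2-Eb1 from 6837 ± 683.5 to 873 ± 179 CPM. Of 12 inflammatory monocyte genes 7 rose (8 adjusted over the list alone; adjusted p = 0.0501 with an estimated correlation), such as the scavenger receptor gene Msr1 by 3.01 log2 and Fcgr1 by 2.71. Of 13 neutrophil genes 9 rose (10 adjusted over the list alone), such as the chemokine receptor gene Cxcr2 by 2.56 and S100a8 by 2.08 (list adjusted p = 0.0287, but adjusted p = 0.348 with an estimated correlation). Without uninjured replicate 1 or injured replicates 1, 2 or 3 it stood at 0.163, 0.0535, 0.123 and 0.0507 (0.000439 to 0.348 over all alternatives).

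Of 5 neutrophil chemoattractant genes 4 rose in CD45+ cells and the call held (adjusted p = 0.00914 with an estimated correlation). Cxcl2 went from 62.7 ± 50.4 to 3222 ± 876 CPM, Ppbp from 5.59 ± 0.662 to 657 ± 188 CPM, and Cxcl3 from 1 to 2323 counts (ratio 2105, 377.5 to 83180). Of 10 monocyte chemoattractant genes 8 rose, such as Ccl7 from 31.2 ± 15.1 to 1720 ± 199 CPM and Ccl2 from 73.4 ± 15.4 to 3488 ± 551 CPM, and 2 (Ccl8 and Cx3cl1, named after their values were seen) fell (adjusted p = 0.11 with an estimated correlation). The cytokine gene Tnf rose from 34.6 ± 4.39 to 686 ± 105 CPM (4.31 ± 0.24, adjusted p = 1e-11). Lists that rose with either correlation were the unfolded protein and integrated stress response (14 of 17 genes; 14 adjusted over the list alone; adjusted p = 0.00312 with an estimated correlation), NRF2 targets (13 of 15; 13 adjusted over the list alone; 0.00312), glycolysis (12 of 16; 14 adjusted over the list alone; 0.00888), provisional matrix (6 of 11; 0.016), matrix proteases and inhibitors (7 of 17; 0.00888) and hypoxia response (8 of 15; 0.0271). Among them, the ferritin genes Ftl1 and Fth1 rose from 3074 ± 247 to 8603 ± 435.5 and from 3399 ± 263 to 8660 ± 147 CPM, the glycolytic enzyme gene Pkm by 2.27 log2, and the matrix genes Thbs1 and Vcan by 6.47 and 5.63 log2. Of 19 mitosis genes 15 fell (16 adjusted over the list alone; adjusted p = 0.568 with an estimated correlation), and of 23 DNA replication genes 12 fell (15 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation).

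In stromal cells (MSC) the comparison asked how the fibroblast-like cells between the fibers responded. Transcripts of DNA replication (22 of 23 genes) and ribosome production (21 of 21) rose, and both lists were called with either correlation (adjusted p = 0.0339 and 0.000442 with an estimated correlation). Cxcl5, a neutrophil chemoattractant gene (chromosome 5, 90759360 to 90761624), rose from 0.316 ± 0.162 to 1517 ± 317 CPM (log2 fold change 12.05 ± 1.89, adjusted p = 0.00041). Mcm3, part of the replicative helicase (chromosome 1, 20802968 to 20820312), rose from 19.4 ± 3.06 to 462 ± 94.5 CPM (4.57 ± 0.18, adjusted p = 5.99e-15). Npm1, a nucleolar protein gene (chromosome 11, 33152287 to 33163206), rose from 237 ± 14.3 to 1567 ± 91.6 CPM (2.72 ± 0.10, adjusted p = 5.99e-15). Gsn, the gelsolin gene (chromosome 2, 35256380 to 35307892), held 8.96% ± 0.491 of all counts of uninjured MSC and 2.40% ± 0.744 after injury (-2.17 ± 0.25, adjusted p = 1.2e-06).

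Of 23 DNA replication genes 22 rose in MSC (22 adjusted over the list alone) and the call held (adjusted p = 0.0339 with an estimated correlation). Mcm5 rose from 11.4 ± 4.24 to 528 ± 132 CPM and Pcna from 30.0 ± 0.599 to 204 ± 60.2 CPM. All 21 ribosome biogenesis genes rose (21 adjusted over the list alone; adjusted p = 0.000442 with an estimated correlation), such as Ncl from 214.5 ± 8.30 to 1144 ± 60.8 CPM. Of 19 mitosis genes 17 rose (18 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation), Cdk1 from 1.77 ± 2.18 to 85.8 ± 54.4 CPM. All 21 ribosomal protein genes (adjusted p = 0.127 with an estimated correlation), 12 of 16 glycolysis genes (adjusted p = 0.0852 with an estimated correlation) and 23 of 25 oxidative phosphorylation genes (adjusted p = 0.112 with an estimated correlation) also rose, among them Ldha, which encodes lactate dehydrogenase A, from 515 ± 47.8 to 2528 ± 174 CPM. One other call went the opposite way, with 1 glycolysis gene falling. Of 5 neutrophil chemoattractant genes 4 rose (adjusted p = 0.142 with an estimated correlation), including Cxcl1 from 57.1 ± 32.2 to 520 ± 72.6 CPM, while Cxcl3 and Cxcl2 had 0 counts before injury and were at least 110-fold and at least 48.0-fold higher.

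Among the largest rises in MSC above the level of injured CD45+ cells were those of Serpinb2 (0 counts before injury, at least 194-fold higher), of Il1rl1, the gene of the interleukin 33 receptor (chromosome 1, 40429570 to 40465415; from 1.10 ± 0.421 to 434 ± 115 CPM), of Saa3 (from 0.370 ± 0.641 to 86.3 ± 26.7 CPM) and of Car4 (2 and 378 counts; ratio 150.5, 41.4 to 1247). Of 15 stromal identity genes 10 fell (11 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation), such as the tetranectin gene Clec3b from 411 ± 52.4 to 36.0 ± 18.2 CPM. Of 15 interstitial matrix genes 11 fell (12 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), such as the elastin gene Eln by -3.25 and Col14a1 by -2.60 log2, and of 11 basement membrane genes 9 fell (10 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), such as the laminin gene Lama2 by -2.40 log2. Of 19 cholesterol synthesis genes 12 fell (13 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation). Of 14 muscle fiber genes 13 fell (adjusted p = 0.112 with an estimated correlation), such as Acta1 from 172 ± 84.7 to 1.19 ± 1.16 CPM and Ttn from 34.4 ± 10.2 to 0.956 ± 0.932 CPM. Without MSC injured replicate 1 the number of genes that fell in MSC was 2258 in place of 3831.

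In muscle stem cells (MuSC) the comparison asked how far the cells had left their resting state by day 1. Genes of quiescence (12 of 12), of satellite cell identity (9 of 15) and of Notch signalling (9 of 14) fell while genes of DNA replication (23 of 23) and ribosome production (20 of 21) rose. These lists were called with either correlation (adjusted p = 0.00246, 0.0229, 0.0243, 0.0214 and 0.00458 with an estimated correlation). Lists that fell share members, such as Heyl in the satellite cell and Notch lists, so their calls are not independent. Calcr, the calcitonin receptor gene (chromosome 6, 3685680 to 3764714), fell from 414.5 ± 27.1 to 72.4 ± 7.92 CPM (log2 fold change -2.52 ± 0.18, adjusted p = 4.04e-10). Myod1, whose product drives entry into the muscle lineage (chromosome 7, 46376474 to 46379099), rose from 349 ± 73.1 to 2245 ± 81.9 CPM (2.69 ± 0.17, adjusted p = 2.48e-08), and Pax7 (chromosome 4, 139737062 to 139833528) fell from 574 ± 69.6 to 227 ± 25.7 CPM (-1.34 ± 0.34, adjusted p = 0.00698). The injury values of Myod1 and Pax7 were chosen after they were seen.

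All 12 quiescence genes fell in MuSC (12 adjusted over the list alone; median -1.56 log2; adjusted p = 0.00246 with an estimated correlation). The quiescence list was also called in MSC, with the preset correlation only. There 7 of 12 genes fell and 1 rose (median -0.97 log2). Of 15 satellite cell genes 9 fell (10 adjusted over the list alone), such as Spry1 and Msc, by -1.86 and -1.99 log2, and 1 (Myod1) rose; the call held (adjusted p = 0.0229 with an estimated correlation). Of 14 Notch pathway genes 9 fell, including the receptors Notch3 from 587.5 ± 37.8 to 152 ± 14.7 CPM and Notch1 from 360 ± 56.2 to 132 ± 11.4 CPM and the target Heyl from 822 ± 115.5 to 291.5 ± 41.7 CPM, and 1 ligand gene, Jag2 (named after its values were seen), rose by 2.33 (adjusted p = 0.0243 with an estimated correlation). All 23 DNA replication genes rose (23 adjusted over the list alone; median 3.49 log2; adjusted p = 0.0214 with an estimated correlation), such as Mcm3 from 46.9 ± 8.27 to 688 ± 77.2 CPM (3.88 ± 0.17, adjusted p = 4.94e-14). Of 21 ribosome biogenesis genes 20 rose (21 adjusted over the list alone; adjusted p = 0.00458 with an estimated correlation). Of 11 provisional matrix genes 7 rose (8 adjusted over the list alone; adjusted p = 0.0422 with an estimated correlation), such as tenascin C, Tnc, from 1.55 ± 1.48 to 284 ± 84.2 CPM and the hyaluronan receptor gene Cd44 from 57.3 ± 2.15 to 582.5 ± 47.4 CPM. Of 19 mitosis genes 18 rose (adjusted p = 0.746 with an estimated correlation), Cdk1 from 12.1 ± 6.81 to 237 ± 91.6 CPM. Of 16 glycolysis genes 12 rose and 1 fell (adjusted p = 0.107 with an estimated correlation).

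The largest rises in MuSC included Nptx1, a neuronal pentraxin gene (chromosome 11, 119538719 to 119547753), with 0 counts before and 70.6 ± 25.5 CPM after injury (at least 303-fold higher), Hmga2 and Traf1 (at least 156-fold and at least 110-fold higher), the asparagine synthetase gene Asns (1 and 2234 counts; ratio 1429, 256 to 56450) and Esm1, the gene of endocan (1 and 1906 counts; ratio 1219, 218.5 to 48170). The largest falls included Tac4 (-3.92 ± 0.69), Nppc (from 90.6 ± 23.5 to 8.11 ± 6.72 CPM) and the collagen gene Col15a1 (from 90.8 ± 17.3 to 10.9 ± 1.06 CPM). Of 18 immediate early genes 10 fell (1 up and 10 down adjusted over the list alone), such as Fos from 1199 ± 212 to 468 ± 103 CPM (list adjusted p = 0.0326, but adjusted p = 0.711 with an estimated correlation). Without uninjured or injured replicate 1 the list stood at 0.0701 and 0.0509 (0.0011 to 0.711 over all alternatives). Chemokine and stromal transcripts were uneven across the injured MuSC libraries. Cxcl5 was at 3.57, 333 and 60.5 CPM and Ccl2 at 22.8, 353 and 191 CPM, beside Pdgfra at 0.298, 48.8 and 25.4 CPM. Without injured libraries 2 and 3, an alternative chosen after seeing the data that leaves 1 injured library, 2219 genes rose and 1807 fell.

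**Figure D3:**
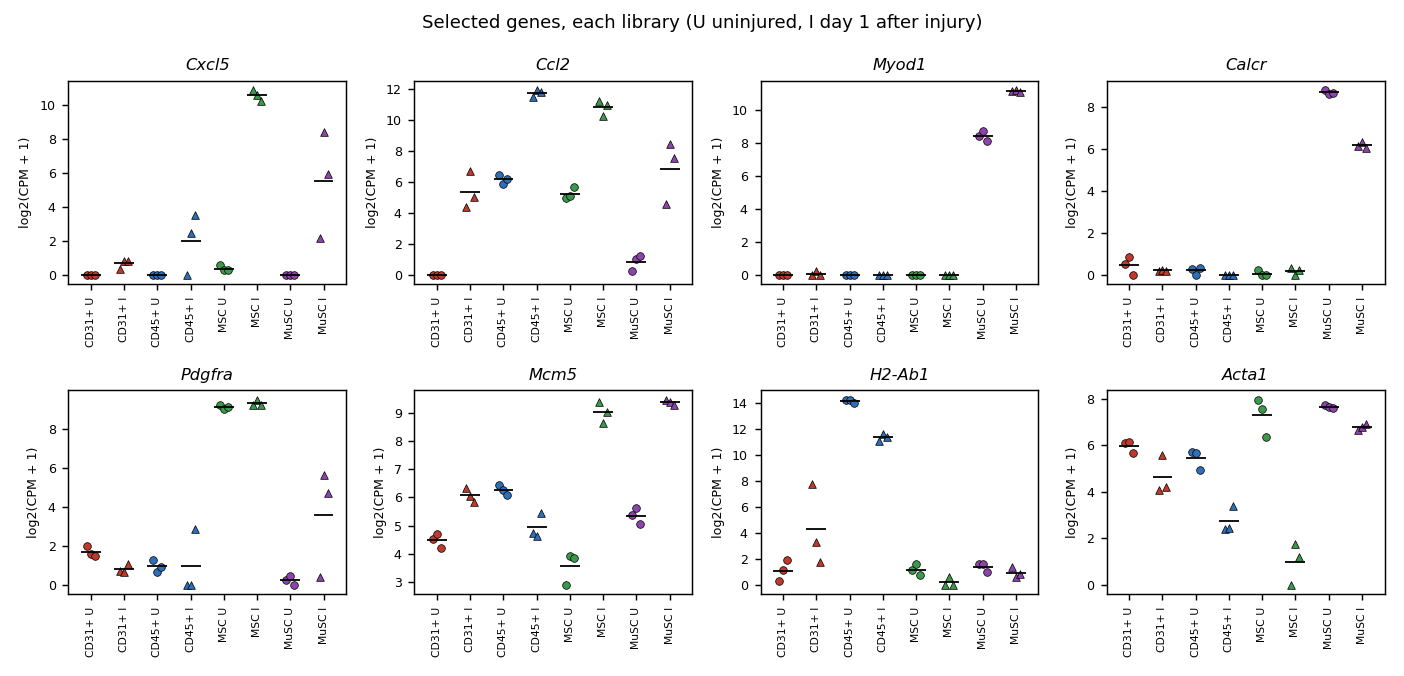
Expression of 8 genes as log2(CPM + 1) in each library of the 8 groups (U, uninjured; I, injured); points are libraries and bars are means. Cxcl5 is highest in injured MSC (mean 1517 CPM) and ranges from 3.57 to 333 CPM over injured MuSC libraries, Myod1 and Calcr are seen in MuSC, and the mean of Acta1 is lower in each injured population than in its uninjured one.

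**Figure D4:**
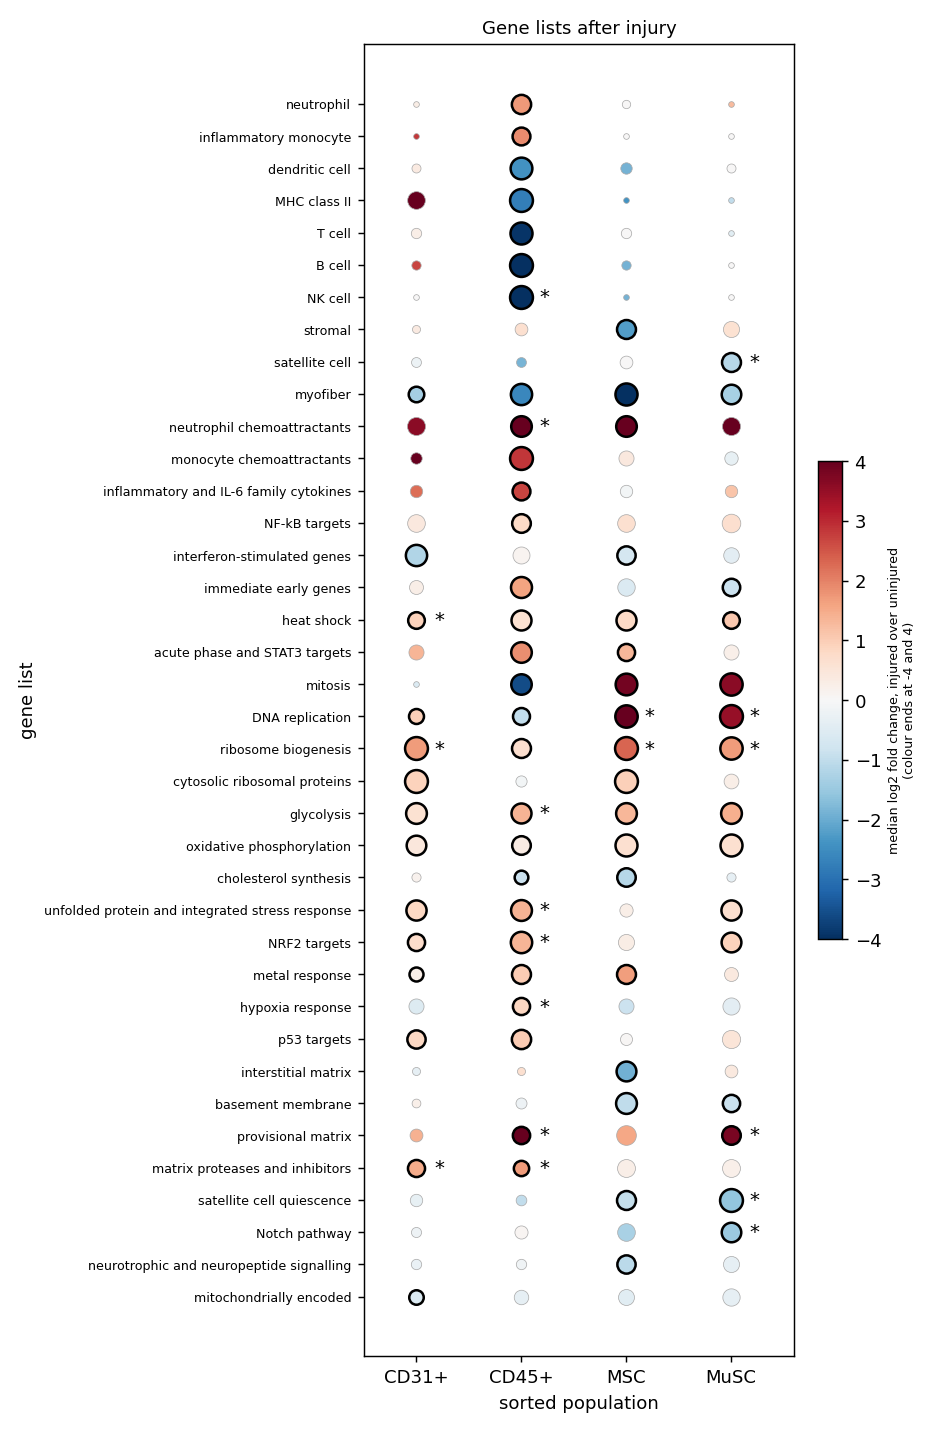
Gene lists (vertical axis) after injury in each sorted population (horizontal axis); color is the median log2 fold change, ending at -4 and 4, and the size of a circle is the share of members that passed the test. Black rings mark lists called by camera with the preset correlation and stars those also called with an estimated correlation (3 in CD31+, 8 in CD45+, 2 in MSC and 6 in MuSC); members with 0 counts in a group enter with their fitted value.

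With the preset correlation, 14 lists were called in CD31+ cells (11 up and 3 down), 28 in CD45+ cells (19 and 9), 18 in MSC (10 and 8) and 15 in MuSC (9 and 6). An estimated correlation left 3, 8, 2 and 6 of them. Splits of the same libraries other than the real one called a median of 14, 18, 12 and 11 lists with the preset correlation. A call that rests on the preset correlation alone is therefore weak evidence. Medians of lists with members at 0 counts in a group rest on fitted values. With those members at their bound, the median of neutrophil chemoattractants was 6.88 in place of 7.72 in CD45+ cells and 5.59 in place of 8.61 in MSC, and that of provisional matrix 1.4 in place of 4.19 in CD45+ cells and 3.35 in place of 3.81 in MuSC.

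The third comparison asked whether the response to injury differed between populations. It did for 5842 of 16263 genes (35.9%) by the F test. The response of CD45+ cells differed from the mean of the others for 4173 genes, that of MSC for 2388, of MuSC for 2194 and of CD31+ cells for 1509. For the mixed CD45+ cells such a difference can also come from a change in the mix of cell types. There the median of B cell genes went from 360 to 4.06 CPM and that of neutrophil genes from 132 to 535 CPM. DNA replication genes moved apart as a group. Against the mean of the others, the injury effect was lower in CD45+ cells for 23 of 23 genes. It was higher for 21 of 23 in MSC and in MuSC. The median differences were -3.37, 2.73 and 2.13 log2 (adjusted p = 0.0035, 0.0117 and 0.0243 by camera with an estimated correlation). For each gene such differences cancel out over the populations by construction, so these calls are not independent. The median injury effects themselves were 0.95, -0.97, 4.01 and 3.49 log2 in CD31+, CD45+, MSC and MuSC. Arg1 rose in CD45+ cells by 7.75 log2 and changed by -0.94, -0.47 and 0.32 in CD31+ cells, MSC and MuSC (difference 8.12 ± 1.11, adjusted p = 1.68e-05). Pgf rose by 5.78 in CD31+ and 5.00 in CD45+ cells and stood at -2.37 in MSC (difference of MSC from the others -6.27 ± 0.54, adjusted p = 4.16e-07). Bmp2 had a difference of 9.68 ± 1.01 in CD31+ cells (adjusted p = 9.52e-07) and Nptx1 one of 10.51 ± 1.69 in MuSC (adjusted p = 0.000188). The uninjured libraries of these populations held 1 and 0 counts, so that the size of both rests on the fit. Without MSC uninjured replicate 3, which left 0 counts in that group, the difference of Nptx1 was 9.36 with an adjusted p of 1 (3.02e-14 to 1 over all alternatives). For genes with a group at 0 counts the test often returned a p of 1. It gave a p over 0.99 to 277, 350, 219 and 196 genes with fitted differences beyond 3 log2 in CD31+, CD45+, MSC and MuSC, and the counts above leave these out. For 1246 genes the test of injury passed with opposite directions in at least 2 populations.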

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

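Of the tests in this part, those on the chemokines and the stromal transcripts in MuSC, both on leukocyte transcripts in CD31+ cells, the count without library 1 and the test of dilution were chosen only after the result was seen, as were the use of bootstrap intervals (95%, 2000 draws) and the count of transcripts below the level a share needs. Groups of 3 libraries were not tested for outlying libraries. The results here stood out because the response to injury differed between populations, by the test of the difference itself. Each value is the injury effect in 1 population minus the mean of the other 3, on the log2 scale, with the adjusted p of edgeR's quasi-likelihood test. Genes were taken by size of the difference. Where a group had 0 counts, named below, the difference is a fitted value whose size the counts do not fix. Ranges of adjusted p over all alternatives are given where a call ended under any of them.

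In CD31+ cells the effect was more positive for Bmp2 (9.68, adjusted p = 9.52e-07), Ighm (8.66, 0.0041), H2-Ab1 (8.04, 0.00981) and Irf4 (7.97, 0.00743). It was more negative for Steap1 (-7.60, 0.0345), Crabp1 (-6.71, 0.0194), Pdpn (-6.08, 0.000186) and Prg4 (-4.87, 0.000142). Groups at 0 counts were uninjured CD31+ for Irf4, injured CD31+ for Steap1, and injured CD31+, uninjured CD45+ and uninjured MuSC for Crabp1. Ighm, H2-Ab1 and Irf4 are transcripts of antigen-presenting and B cells and fell in CD45+ cells by 4.10, 2.78 and 3.74 on the log2 scale. In injured CD31+ libraries 1 to 3 H2-Ab1 was at 214, 8.54 and 2.38 CPM and Ighm at 15.1, 20 and 0 CPM. Irf4 was at only 0.923, 2.33 and 0.317 CPM there, where 3 counts equal 0.467, 0.581 and 0.512 CPM. Without CD31+ injured replicate 1 the difference of H2-Ab1 was 4.22 in place of 8.04. With voom the adjusted p was 0.074 for Ighm, 0.101 for H2-Ab1 and 0.122 for Pdpn, the highest over all alternatives, whose lowest were 2.38e-06, 1.88e-07 and 4.23e-11. The call of Crabp1 ended without CD31+ uninjured replicate 2 or 3 (adjusted p = 0.0737 and 0.0792). That of Steap1 ended without CD31+ uninjured replicate 1 or 2 (0.303 and 0.0707) or injured replicate 1, 2 or 3 (0.0613, 0.0564 and 0.0604). Both became 1 without CD45+ injured replicate 3, as did Irf4 without MuSC uninjured replicate 2, where a group was left with 0 counts. The ranges were 0.0014 to 1 for Crabp1, 9.74e-05 to 1 for Steap1 and 4.46e-08 to 1 for Irf4.

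In CD45+ cells the effect was more positive for Arg1 (8.12, adjusted p = 1.68e-05), Dmkn (7.48, 0.00614), Prokr1 (7.46, 0.00102) and Nt5e (7.25, 5.81e-06). It was more negative for Pla2g2d (-11.46, 0.000142), Il1rl1 (-10.08, 0.00328), Slc10a6 (-8.61, 1.83e-05) and Slc14a1 (-8.55, 0.00818). Groups at 0 counts were uninjured CD45+ for Prokr1, uninjured MuSC for Il1rl1, injured CD45+ for Slc10a6, and uninjured CD31+, MSC and MuSC for Slc14a1. Il1rl1 fell from 55.1 ± 23.1 to 5.73 ± 4.29 CPM in CD45+ cells while it rose to 434 ± 115 CPM in MSC. Its adjusted p was 0.0953 without CD31+ injured replicate 3 (range 2.03e-08 to 0.0953). Leaving out CD31+ uninjured replicate 2 (Dmkn and Prokr1) or MSC injured replicate 3 (Slc14a1) left a group with 0 counts and gave an adjusted p of 1. The ranges were 6.16e-06 to 1 for Dmkn, 1.24e-06 to 1 for Prokr1 and 2.59e-06 to 1 for Slc14a1.

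In MSC the effect was more positive for Ube2t (8.71, adjusted p = 8.18e-06), Cdca7l (6.93, 5.02e-07), Ncapg (6.43, 0.00103) and BC030867 (6.19, 0.00129). It was more negative for Gdf15 (-7.51, 0.000241), Ighm (-6.44, 0.0182), Pgf (-6.27, 4.16e-07) and Pitpnm3 (-6.10, 0.00466). Groups at 0 counts were uninjured MSC for Ube2t, uninjured MuSC for Gdf15, and injured MSC and uninjured MuSC for Pitpnm3. Gdf15 had a fitted effect of 6.96 in CD31+, 5.16 in CD45+ and 5.02 in MuSC against -1.80 in MSC. Without MuSC injured replicate 3 the adjusted p was 0.242 for Ighm and 1 for Pitpnm3, which then had a group with 0 counts. The ranges were 0.00039 to 0.242 for Ighm and 0.000555 to 1 for Pitpnm3.

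In MuSC the effect was more positive for Nptx1 (10.51, adjusted p = 0.000188), Traf1 (9.28, 4.94e-06), Cd36 (8.16, 0.000633) and Hmga2 (7.97, 0.00618). It was more negative for Bst1 (-7.48, 0.00762), Ppbp (-7.02, 0.0283), Soat2 (-6.10, 0.0475) and Apln (-5.60, 0.00166). Groups at 0 counts were uninjured MuSC for Nptx1, Traf1, Cd36 and Hmga2, injured MuSC for Bst1 and Soat2, and uninjured MSC for Bst1 and Ppbp. Nptx1 and Hmga2 had an adjusted p of 1 without MSC uninjured replicate 3, which left that group with 0 counts (ranges 3.02e-14 to 1 and 2.78e-05 to 1). Bst1 had 0.237 without MuSC uninjured replicate 1 (2.23e-08 to 0.237), with a difference of -4.86. Ppbp had 1 without MSC injured replicate 1, 0.0522 and 0.062 without MuSC uninjured replicates 2 and 3, and 0.0539 without MuSC injured replicate 3 (1.26e-06 to 1). Soat2 lost its call without CD31+ uninjured replicate 3 (0.0568) or injured replicates 2 and 3 (0.0558, 0.0581), and without CD45+ uninjured replicates 1 and 2 (0.0542, 0.059). It also did without MSC uninjured replicates 2 and 3 (0.0517, 0.0505) or injured replicate 2 (0.0603), and MuSC uninjured replicate 3 (1, with a difference of -3.28) or injured replicates 1 to 3 (0.0848, 0.075, 0.084), with a range of 0.00252 to 1.

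Gene lists whose response differed with either correlation are given by the median difference of their members and the adjusted p with an estimated correlation. For each gene the differences cancel out over the populations by construction, so opposite calls of a list in different populations are not independent. CD45+ cells had lower effects for DNA replication (-3.37, 0.0035) and ribosome biogenesis (-1.29, 0.00611) and higher ones for NRF2 targets (1.06, 0.048) and the hypoxia response (1.19, 0.0027). MSC had higher effects for DNA replication (2.73, 0.0117) and ribosome biogenesis (0.90, 0.0117) and lower ones for the unfolded protein and integrated stress response (-0.67, 0.0398) and the hypoxia response (-0.94, 0.0244). MuSC had higher effects for DNA replication (2.13, 0.0243) and lower ones for the Notch pathway (-0.99, 0.0243).

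Injured MuSC libraries 2 and 3 held stromal and chemokine transcripts far above library 1: Dcn was at 16.7, 354 and 256 CPM in libraries 1 to 3 and Cxcl5 at 3.57, 333 and 60.5 CPM. MSC carried over with their average injured profile are argued against as the source of the genes higher in injured MuSC, since 96.7% of these (96.1 to 97.3) rose by more than 10% of their level in injured MSC, and the 50 abundant MSC transcripts needed a median share of 3.92% and 2.62% in libraries 2 and 3. For the stromal transcripts, at the lower bootstrap limit of that share (2.93% and 1.6%), 9 and 5 of the 50 lay over 3 times below the level needed. This was by their upper counting limit, such as Cd248 with 0 and 1 counts. No transcript differed so far between the MSC libraries, but each of those held about 1000 sorted cells. So small a share would be few cells, whose makeup can differ from the average. Ly6a, which encodes Sca1, was among the low transcripts in each library, and MuSC were sorted without Sca1. The test therefore cannot decide whether MSC were the source of the stromal transcripts. At the lower limit of the share that the chemokines need (16% and 3.99%, with medians of 45.5% and 9.25%), 26 and 9 of the 50 lay as far below. In library 2, where this share is large, that argues against MSC with the average injured profile as the source of the chemokines. In library 3 this share can be small, and the test cannot decide for the same reason. A subset of MSC with another profile, other cells, and a response of MuSC to injury that differs between samples stay open as untested.

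Injured CD31+ library 1 held leukocyte transcripts, with Lyz2 at 108 CPM against 1.75 and 0.159 CPM and Cd74 at 135 CPM against 16.1 and 1.11 CPM in libraries 2 and 3. For leukocytes with the average injured CD45+ profile, the median share was 0.614% (lower limit 0.454%). At that lower limit 4 of 50 abundant transcripts lay over 3 times below the level needed, by their upper counting limit. They were Spp1, Arg1, Ccl7 and Cxcr2, and Arg1 had 1 count. No transcript differed so far between the injured CD45+ libraries, but each of those held about 1000 sorted cells. So small a share would be few cells, whose makeup can differ from the average, and the limits cover counting error only. The test therefore cannot decide on this source, which stays open. For the average uninjured CD45+ profile, at a median share of 0.829%, 2 of 50 lay as far below at its lower limit of 0.677%. That was as many as between the uninjured CD45+ libraries. The ratio of upper to lower quartile of the shares was 2.63 (1.80 to 3.92) around a bound of 3, which leaves carry-over of leukocytes like these open. That library 1 alone decides the number of genes higher in injured CD31+ cells is argued against, since 1933 genes were higher without it and 2298 with it. Leukocytes of another makeup were not tested, and no biological explanation was tested for a single library.

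Muscle fiber transcripts had lower medians after injury in all 4 populations: of 14 genes 6 fell in CD31+, 12 in CD45+, 13 in MSC and 9 in MuSC, with a median fall of 2.56-fold, 6.12-fold, 33.0-fold and 2.49-fold. In MuSC 1 of the 14 genes rose. The list's calls were lost in each (adjusted p = 0.351, 0.138, 0.112 and 0.63 with an estimated correlation), and in MuSC also without uninjured replicate 2 (0.06), injured replicate 2 (0.128) or injured libraries 2 and 3 (0.195; 0.000245 to 0.63 over all alternatives). A larger total of other RNA that dilutes 1 constant amount of fiber RNA by the same factor in every population is argued against. The largest fall was 13.3 times the smallest (4.99 to 38.2), beyond the bound of 3. Dilution by a factor that differs between populations was not tested. Medians after injury were only 2.1, 1.24 and 0.725 CPM in CD31+, CD45+ and MSC. Free RNA of fibers in every sort stays open: the lowest correlation across the 14 genes of log2 levels in uninjured cells between a pair of populations was 0.51 (-0.143 to 0.778) and the highest 0.879, and genes are not independent replicates. Transcription by the sorted cells themselves, with 4 of the 14 genes highest in uninjured MuSC, and a loss of fibers after the toxin were not tested.

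Other splits of the same libraries were tested in the same way as the real one. For injury the 6 libraries of a population allow 10 splits, too few for a share below 0.05. The real split called 3810, 5606, 6808 and 6318 genes in CD31+, CD45+, MSC and MuSC, and the highest other split 1, 32, 1 and 1, so that 1 split of 10, the real one, reached the real count in each. For gene lists the real numbers were 14, 28, 18 and 15 and the highest others 17, 23, 16 and 16, with 6, 1, 1 and 4 of 10 splits as large. The other splits called a median of 14, 18, 12 and 11 lists, though they called few genes. A list called with the preset correlation alone is therefore weak evidence of an injury effect. Of 100 splits of the 12 uninjured libraries, 2, 1, 1 and 1 gave as many genes highest in CD31+, CD45+, MSC and MuSC as the real 1614, 2221, 1479 and 1282 (highest others 1756, 1052, 767 and 0). These splits mix libraries of different cell types, so they show only that the populations differ. No conclusion on chance is drawn from them for the count of a single population. The 91 splits that kept no real group whole called 0 genes. For differences in response, 2 of 100 splits reached the 5842 genes of the test over all populations (highest other 6505). In CD31+, CD45+, MSC and MuSC, 2, 1, 3 and 2 reached the 1509, 4173, 2388 and 2194 genes of the real split (highest others 4102, 2779, 2985 and 3695). These splits exchanged injury labels within populations, which takes away the injury effect itself. They cannot tell a difference in response from an injury effect that all populations share, so they do not settle whether chance made the counts. The splits with the largest counts kept 1 to 3 real groups whole, which points to the structure of the samples. The 71 splits that kept none called at most 2 genes.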

How the results depend on the processing

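In this part the alternatives without Gm10800, Gm10801, Gm42418 and Gm26917 and without injured MuSC libraries 2 and 3 were chosen only after the data were seen. Of 434 results for named genes, 298 kept their direction and their side of the threshold under every setting run, and of 75 called lists 19 did. Over all settings, genes gave 6756 values on the same side, 214 that lost and 39 that gained a call, and 14 that changed sign. Lists gave 832 on the same side and 81 that lost their call. The test against a 2-fold change made 87 of the losses of genes. Of the genes, 47 lost a call by another setting, 26 of them by leaving out 1 library, and of the lists 56 did, 10 of them by leaving out 1 library. DESeq2 gave no adjusted p for 1 result. The cause was not tested unless stated.

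Changes of sign were all in sort gate genes whose result had not passed. They were Pecam1 in CD31+ with no filter on low counts (0.0724 log2); Pdgfra in CD45+ with voom (-1.14) and without injured replicate 3 (-5.41), the only injured library with counts; Vcam1 in CD45+ without injured replicate 3 (-0.0189); Ptprc in MSC without uninjured replicate 1 (1.67). Ptprc in MuSC changed sign with RLE (-0.00453), DESeq2 (-0.019), voom (-0.498), without injured libraries 2 and 3 (-3.36), and without uninjured replicate 1 (-0.562), uninjured replicate 2 (-0.25) or injured replicate 3 (-3.30). Leaving out 1 library in turn spanned -5.41 to 1.75 log2 for Pdgfra and -0.0189 to 1.71 for Vcam1 in CD45+, -1.76 to 1.67 for Ptprc in MSC and -3.30 to 3.42 for Ptprc in MuSC.

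Counts moved by more than 1.5 times as follows. Tested against a 2-fold change, which asks for more by construction, 820, 1283, 717 and 422 genes were highest in uninjured CD31+, CD45+, MSC and MuSC. Injury then called 337 higher and 56 lower genes in CD31+, 434 and 1074 in CD45+, 919 and 1129 in MSC and 1120 and 399 in MuSC. In CD31+ the genes lower were 1007 with no filter and 2353 with DESeq2. The genes higher were 1363 when genes higher in injured CD45+ were left out, which removes genes by construction, and those whose response differed 2357 with DESeq2. Leaving out 1 library in turn gave 2258 to 3389 genes lower in MSC. Without injured MuSC libraries 2 and 3, which leaves 1 library assumed to vary like the others, 2219 genes were higher and 1807 lower in MuSC. Called lists numbered 25, 29 and 24 with no filter in CD31+, MSC and MuSC, 28, 39 and 31 with fry, which asks another question, and 3, 8, 2 and 6 in CD31+, CD45+, MSC and MuSC with an estimated correlation. The other counts stayed within 1.5 times.

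By the check of deviations from group means, libraries with the same muscle number were weakly alike within a condition. In different populations of 1 condition their median r was 0.0185 (-0.0142 to 0.133, 3 of 36 pairs over 0.1). For different numbers it was -0.0111 (-0.134 to 0.0413, 0 of 72 pairs over 0.1). Of 24 libraries, 20 correlated best with their own number of the 3, more than numbers without meaning would give on average. Across conditions the same number had a median r of -0.0232 over 12 pairs. Whether the numbers mark the same mouse stays open, and the main fit treats all libraries as independent. If they do, the tests between populations take no account of that pairing, and their p-values would be approximate. With the number as a block, 2247 genes were higher and 1472 lower in CD31+, 2545 and 2881 in CD45+, 2930 and 3736 in MSC and 3426 and 2731 in MuSC, and no count moved by more than 1.5 times. That block joins the same number across conditions, where libraries were not alike. It is therefore a weak check on a pairing of populations within a condition. The differences of Soat2 in MuSC (0.0616, and 0.0737 with condition and number as a fixed block) and of Ighm in MSC (0.0518 with the latter) had adjusted p over 0.05 under a block. With condition and number as a random block Pdgfra in CD45+ (-1.16) and Ptprc in MuSC (-0.454) changed sign.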

Other observations

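The permutation test and the genes named in this part were chosen only after the data were seen. The responses to injury shared many genes. By the test within each population, 814 genes rose in all 4 populations, where independent lists of the same sizes would share 14, and 307 fell in all 4 (12). MSC and MuSC shared 2321 rising genes (636 if independent) and 1851 falling ones (669), and CD31+ and CD45+ cells 1159 (367) and 584 (280). The counts if independent take no account of expression level, and the cause of the excess was not tested. Among the genes with the largest smallest effect, Timp1, which encodes an inhibitor of metalloproteases (chromosome X, 20870166 to 20874735), rose by 5.93, 7.58, 5.50 and 5.95 log2 in CD31+, CD45+, MSC and MuSC. The interleukin gene Il6 rose by 4.03, 4.15, 5.84 and 6.12, the transcription factor gene Fosl1 by 4.13, 4.06, 5.77 and 7.90, and the growth factor gene Hbegf by 3.92, 2.24, 3.05 and 4.03. The cardiac actin gene Actc1 fell by 5.29, 5.79, 5.78 and 2.34 on the log2 scale.

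Counts assigned to 2 gene models of satellite repeats, Gm10800 and Gm10801 (chromosome 2, 98666547 to 98667301 and 98662237 to 98664083, GRCm38), made up a share of all counts that was lower after injury in each population. The share was 7.38% ± 1.71 uninjured and 3.26% ± 0.242 injured in CD31+, 3.37% ± 0.480 and 2.06% ± 0.0144 in CD45+, 0.913% ± 0.101 and 0.321% ± 0.0835 in MSC, and 2.31% ± 0.277 and 0.759% ± 0.0782 in MuSC (SD, n = 3). A two-sided exact permutation test that exchanged libraries within populations gave p = 1.25e-05 over 160000 assignments, the smallest it can give (adjusted over 3 shares 3.75e-05). The same exact permutation test gave p = 0.000838 (adjusted 0.00126) for the share of mitochondrial transcripts, which went from 1.12% to 0.880% in CD31+, from 1.52% to 0.959% in CD45+ and from 2.56% to 2.01% in MuSC but from 1.31% to 1.395% in MSC. The exact permutation test gave p = 0.155 for the share of ribosomal RNA models. Counts alone do not separate RNA from genomic DNA or from reads that match several places, so the shares of the satellite models are shares of counts and not of transcripts.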
